A study of Mus musculus with 2 samples.

How the data were processed

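The series measured acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was whole lung of B6NCrl mouse embryos at embryonic day 15.5. Per the labels, there were 2 biological replicates, each a pool of male and female embryos: 78 embryos in replicate 1 and 62 in replicate 2, with library fragments of 300 to 500 bp. Both samples form 1 group. The 2 pools carry the same donor label, which was taken to name the strain, and they were treated as separate pools because the labels number them as biological replicates with different embryo counts. P-values over genes or peaks describe these 2 pools and not a wider population of mice.

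The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly: 1 per replicate, 1 called on both replicates pooled, and a list of replicated peaks. Per the deposited notes, each replicate was called against its own control file, the pooled list used both, and the replicated list was derived from the other 3. The rule that keeps a peak in the replicated list, the aligner, the peak caller and its threshold are not given in the sources used here. The deposited signal value of a peak was read as a linear ratio, the fold enrichment of ChIP over control, which is an inference from the values and the usual content of this column; the notes do not define it, and the format asks only for a measure of enrichment. The deposited significance values are −log10 p and −log10 q per peak. The lowest −log10 p was 2.01 in the list of replicate 1 and 2.05 in that of replicate 2. A −log10 q below 2 was held by 17.6% and 19.1% of their peaks, and by 0.635% of the replicated peaks. Peaks called in a single replicate's own list can thus be weak. The display score that the authors deposited for each peak was not used. The deposited summit position, in bp from the peak start, centred the windows of the sequence test. The signal value belongs to the peak as the authors called it, and it served only to describe, rank or filter peaks within a list.

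Read counts and sequencing depth were not analysed here, so the depth of each pool is unknown and no interval for a single peak can be given. A gene without a peak is therefore a gene without a call at this depth, which may still carry acetylation. Confidence intervals are 95% exact binomial (Clopper-Pearson) intervals over genes or peaks and cover counting error only.

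Genes came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and sequence from GRCm38.p6. All 21829 protein-coding genes on the 19 autosomes, X and Y were used. A gene had a promoter peak when a replicated peak overlapped by at least 1 bp the 1 kb on either side of any of its protein-coding transcript starts. Replicated peaks outside all such windows were called distal and assigned by their midpoint to the nearest protein-coding transcript start within 100 kb. Nearest-gene assignment is a convention and does not show which gene an element acts on. The 8 replicated peaks outside the main chromosomes were left out of every comparison. No list of artefact-prone regions was applied here.

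Before the data were examined, 29 gene lists holding 484 distinct protein-coding genes, the tests, most alternatives and the rule for named genes were fixed. The lists cover 8 lung cell populations, 3 populations that reside in or pass through lung, 8 other organs, 7 signalling or matrix groups and 3 control groups. Some genes stand in several lists. The genes named are 31 landmark genes, the 3 members of each list with the highest promoter signal (mean of both replicate lists) among those with a replicated promoter peak, the first 2 members in alphabetical order with none, the nearest genes of the 10 top-ranked domains, and the 10 genes with the longest summed peaks. Hox genes are named as members of the groups compared. Genes named for another reason are said to have been chosen after their values were seen.

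Promoter lists were compared with all other protein-coding genes by two-sided Fisher's exact tests. For every odds ratio given here, 0.5 was added to each count, which draws ratios from small lists towards 1. Distal peak length per gene was compared with 100000 random lists of genes from the same decile of territory, meaning the sequence nearer to that gene than to any other within 100 kb, in two-sided permutation tests. The smallest p these permutations can give is 2e-05. Lung and other-organ lists were set against each other by Fisher's exact test and by permuting the class of genes within territory deciles, two-sided, where the smallest p is 1e-05. Hox genes of paralog groups 1 to 5 were compared with groups 9 to 13 by Fisher's exact test. Replicated peaks over 2.5 kb from a transcript start were joined within 12.5 kb into domains, which were ranked by the sum of length times signal. Top-ranked domains are those beyond the point where the ranked curve, scaled to unit axes, reaches a slope of 1. Gene lists were then tested for nearest genes of top-ranked domains by Fisher's exact test, without matching on territory.

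Consensus words of 26 transcription factor families were searched on both strands within 250 bp of the summit of each distal peak. The same number of control windows came from flanks 2 to 20 kb away, outside all 4 peak lists, matched on GC content in bins of 2 percentage points. Mean GC content was 48.1% in peak windows and 48.1% in control windows. Replicates were compared by exact McNemar tests on genes with a promoter peak in a single replicate, and each list's split was set against that of all genes by Fisher's exact test, which the few such genes per list left without power. Benjamini-Hochberg adjustment was applied over the 29 lists or the 26 words, with 0.05 as threshold.

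Alternatives were the pooled list, stricter cut-offs (−log10 q of at least 5, or signal of at least 5), each replicate's own list, promoter windows of 500 bp and 2.5 kb, at least 500 bp of the window covered, random genes matched on promoter CpG content, distance limits of 50 and 500 kb, peak number in place of length, no territory matching, joining within 5 kb, the top 500 domains, ranking by length alone, word windows of 100 bp either side or the whole peak, and the reversed word. Matching on territory and CpG content together was added after the data were seen.

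The scripts were tested on simulated data. With lists of 20 genes each planted among the 21829 genes, the promoter test called 8 of 10 lists with 90% of members carrying a peak, 10 of 10 at 100%, 4 of 10 at 30% and 10 of 10 at 10%. It called 0 of 20 lists without a planted change. The distal test called 0 of 10 lists at a planted 2-fold excess, 2 of 10 at 3-fold and 0 of 20 without one, so its power for single lists is low. The class contrast, on 240 genes, recovered 12 of 20 planted 2-fold excesses and called 1 of 20 sets without one. The word test called a word planted in 5% of 20000 windows and did not call it when none was planted. Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.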

Results

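H3K27ac was profiled in whole mouse lung at embryonic day 15.5, when the airways are still branching and the distal tips hold epithelial progenitors. The data come from 2 pools of embryos (78 and 62 embryos, n = 2 pools), with no second tissue, stage or treatment. The comparisons are therefore between the replicates, and between groups of genes within the same tissue. Replicate 1 held 98685 peaks covering 57.2 Mb and replicate 2 held 96860 covering 55.1 Mb. The pooled list held 110910 peaks over 72.5 Mb. The replicated list, used for every gene-based result, held 64363 peaks over 60.5 Mb, with a median length of 649 bp and a median signal of 4.49. Signal here is the authors' value per peak, read as fold enrichment over control, and it is given for replicate 1 and then replicate 2 beside named promoter peaks. A gene said to have none, or not to be marked, had no promoter peak in the replicated list. Of those named, Sox7 had a promoter peak in both replicates' own lists (3.26 and 2.76), Twist1 (3.17), Synpo2 (4.04) and Dll3 (3.28) in that of replicate 1, and Wt1 (2.07), Nkx6-1 (2.90), Gata4 (2.64), Lgr5 (3.26) and Lama1 (2.72) in that of replicate 2.

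The first question was whether the 2 pools carried the same acetylated regions. The promoters of lung regulators had peaks in both: signal was 20.8 and 22.1 at Nkx2-1, the homeobox factor that marks the lung lineage, 32.0 and 26.5 at the mesenchymal forkhead gene Foxf1, and 36.5 and 37.4 at Ptch1, the hedgehog receptor and target. At Foxa2, a forkhead factor of endoderm, the signal was lower in replicate 1 (11.8) than in replicate 2 (21.7). Peaks of replicate 2 overlapped 66.9% of the replicate 1 peaks (66005), and 69.3% of the replicate 2 peaks (67138) were overlapped in turn. Both lists shared 40.0 of the 72.2 Mb that either covered (Jaccard index 0.554). Sharing rose with signal, from 40.5% in the lowest to 98.9% in the highest quartile of replicate 1 peaks, and from 44.0% to 99.1% for replicate 2. Over the 56076 replicated peaks present in both (87.1%), signal correlated across peaks with a Spearman coefficient of 0.744, where peaks are not independent replicates. The log2 ratio of replicate 1 to replicate 2 had a median of 0.07 (interquartile range −0.22 to 0.35), and 81.3% of these peaks lay within 1.5-fold.

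**Figure D1:**
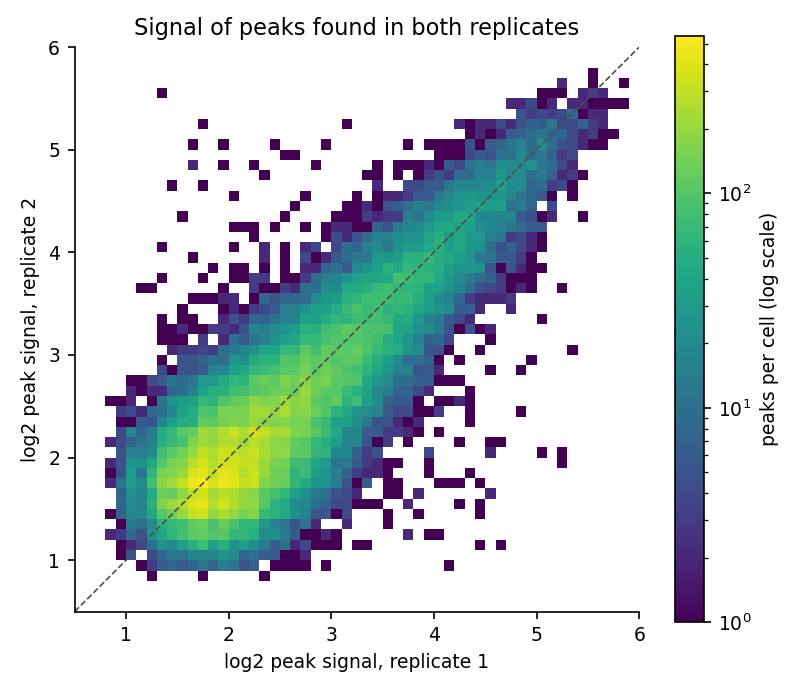
Signal of replicated peaks present in both replicates, as log2 of the authors' fold enrichment in replicate 1 (x axis) and replicate 2 (y axis); colour gives the number of peaks per cell on a log scale and the dashed line marks equal signal. The peaks scatter around the line (Spearman coefficient 0.744).

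Few promoters carried a peak in a single pool. In both replicates 11688 genes had a promoter peak, against 506 in replicate 1 alone and 558 in replicate 2 alone (exact McNemar p = 0.118). With lists cut to the same number of top peaks the counts were 498 and 575, and that difference passed the threshold (exact McNemar p = 0.0203). The 29 lists could not be compared between the pools, since each held at most 3 genes with a peak in 1 replicate alone. With so few the Fisher's exact test could not reach the threshold (smallest p 0.251, 0 lists after adjustment and 0 at an unadjusted p below 0.05). The mixed sex named in the labels could be checked at sex-linked genes. Xist, the RNA of the inactive X chromosome, carried a peak with signals of 7.21 and 6.53. The Y-linked genes Ddx3y (7.21 and 6.26) and Uty (4.33 and 5.17) had promoter peaks, and Eif2s3y and Kdm5d had none. This small list of 4 Y genes (2 with a peak) did not differ from other genes (Fisher's exact adjusted p = 1).

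Promoters held a minority of the peaks but had the highest median signal. Of the 64355 peaks on the main chromosomes, 24.7% lay within 1 kb of a transcript start (95% interval 24.4 to 25.0), 2.49% in exons, 39.7% in introns and 33.1% between genes. Promoter peaks had a median signal of 7.66, against 4.00 in exons, 4.05 in introns and 4.21 between genes, and covered 31.9% of the acetylated sequence. At a signal of at least 5 the promoter share was 41.8%. The longest total acetylation, counting promoter and nearest distal peaks, belonged to Gse1 (82.5 kb), Bcas3 (81.3 kb), Tns1 (80.3 kb), Mecom (72.5 kb), Nfib (68.1 kb), 2010111I01Rik (64.9 kb), Rbpms (61.7 kb), Frmd4a (61.7 kb), Foxp1 (60.4 kb) and Smad7 (59.7 kb). Nfib and Foxp1 encode transcription factors required for lung maturation and epithelial growth, Tns1 a focal adhesion protein, and Smad7 the inhibitory SMAD of TGF-beta signalling.

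Genes on the list for the distal epithelium, the progenitor population of the branching tips, were marked without exception. Peaks from whole lung do not show which cells carried the mark. Nkx2-1 (chromosome 12, 56531958 to 56536908) lay under a promoter peak at 56532838 to 56539076 and had 12 distal peaks totalling 18.5 kb. A cluster of 13 further peaks lay downstream of the gene, at 56400469 to 56440481. The strongest promoters of the list were Id2, an inhibitor of basic helix-loop-helix factors (28.7 and 29.1), the Iroquois homeobox gene Irx3 (25.1 and 25.9), and Foxp2, a forkhead repressor (23.9 and 25.8). Gata6 (14.8 and 23.1), Sox9 (16.4 and 12.1), Shh (20.2 and 22.6) and the FGF-responsive ETS factor Etv5 (13.6 and 10.4) also had promoter peaks. All 22 members carried one, against 54.4% of other genes (odds ratio 37.7, Fisher's exact adjusted p = 2.3e-05).

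**Figure D2:**
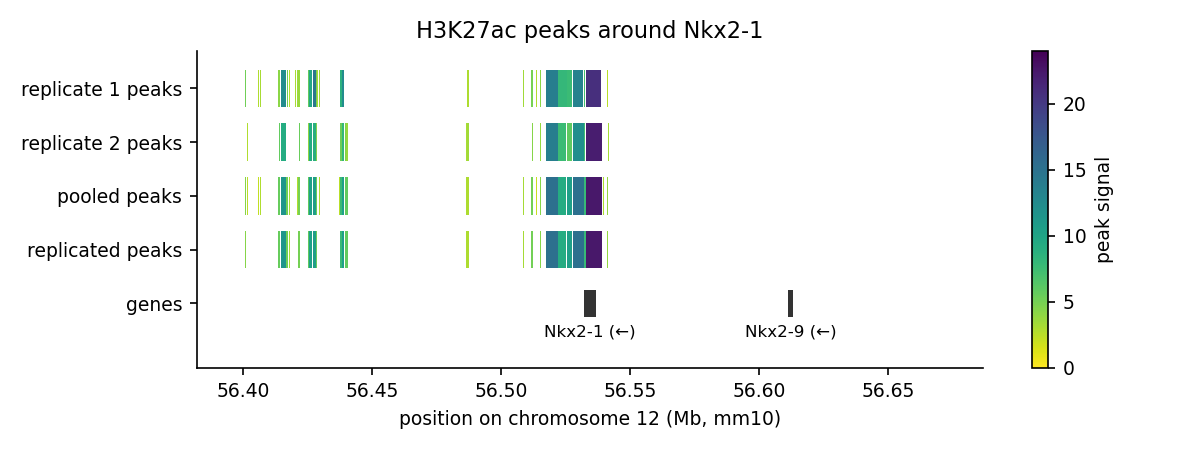
Peaks in the 305 kb around Nkx2-1 on chromosome 12 (mm10), with position in Mb on the x axis, 1 row per peak list and 1 row for protein-coding genes with their strand; colour gives the authors' peak signal. The 26 replicated peaks form a block over the gene and its downstream flank and a second group farther downstream.

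Other epithelial lists were less complete. Among genes of the alveolar epithelium, the promoter signal was highest at Lpcat1, an enzyme of surfactant lipid synthesis (23.1 and 21.7), the factor Cebpa (12.9 and 13.8) and the mucin Muc1 (12.4 and 13.5). Sftpc, which encodes surfactant protein C, had a weaker peak (4.44 and 4.59), and the water channel Aqp5 and surfactant protein A gene Sftpa1 had none. In all, 14 of 18 alveolar genes had a promoter peak, which did not pass the threshold (odds ratio 2.69, exact adjusted p = 0.0697). It did in the pooled list (exact adjusted p = 0.0448), in replicate 2's own list, without replicate 1 (exact adjusted p = 0.0389), and against random genes of equal promoter CpG content (adjusted permutation p = 0.00567). Airway genes carried peaks in 6 of 18 cases (exact adjusted p = 0.111). These included the ciliary regulators Rfx3 (29.1 and 40.5) and Foxj1 (6.17 and 7.13) and the airway progenitor factor Sox2 (4.72 and 5.99), but not the neuroendocrine genes Ascl1 and Calca. The airway share passed below other genes at a −log10 q of at least 5 (exact adjusted p = 0.0487), with 500 bp windows (0.0414) and with at least 500 bp covered (0.0416), but stood at 9 of 18 in the pooled list (0.560).

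Mesenchymal, muscle and endothelial genes were marked more often than other genes. In lung mesenchyme 21 of 23 genes had a promoter peak (odds ratio 7.2, Fisher's exact adjusted p = 0.000576). The highest were Foxf1, the T-box gene Tbx3 (24.6 and 23.2) and Macf1, a crosslinker of the cytoskeleton (23.0 and 22.0). Fgf10, the growth factor that drives branching (5.57 and 8.71), Tbx4 (13.6 and 13.5), Tbx5 (14.2 and 11.6), Wnt2 (5.64 and 10.9), Tcf21 (15.2 and 11.5) and Pdgfra (8.45 and 12.2) were marked, and Nkx6-1 and Twist1 were not. Smooth muscle genes had a peak in 13 of 15 cases (odds ratio 4.52, exact adjusted p = 0.0241), led by Srf, the regulator of contractile genes (20.7 and 21.9), smoothelin (Smtn, 16.4 and 15.4) and the actin gene Acta2 (10.5 and 11.3). Myocd, the cofactor of Srf, had a weaker peak (4.96 and 4.44), and Hspb1 and Synpo2 had none. The smooth muscle call was lost in 3 alternatives: among peaks with a signal of at least 5 (odds ratio 1.74, exact adjusted p = 0.37), at a −log10 q of at least 5 (0.0524) and with at least 500 bp of the window covered (0.0861). Endothelial genes had a peak in 18 of 20 cases (odds ratio 6.19, exact adjusted p = 0.00232), led by the TGF-beta co-receptor gene Eng (10.2 and 10.8), the ETS factor Fli1 (9.91 and 10.2) and the adhesion gene Esam (11.5 and 7.77). The VEGF receptor gene Kdr (4.66 and 8.58), Erg (7.34 and 4.81) and Sox17 (8.34 and 4.90) were also marked, and Car4 and Sox7 were not.

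The remaining lung lists did not pass. Of the lymphatic genes 4 of 7 had a peak (exact adjusted p = 1), among them Nr2f2 (28.5 and 35.1), Lyve1 (3.89 and 6.26) and Prox1 (4.61 and 4.08), whereas Ccl21a and Flt4 had none. Of the mesothelial genes 2 of 10 did, Krt19 (10.9 and 10.2) and Upk1b (4.68 and 3.81), and Wt1, Aldh1a2 and Gpm6a did not (Fisher's exact adjusted p = 0.0644). The mesothelial share passed below other genes against random genes matched on CpG content (adjusted permutation p = 0.0262), at a signal of at least 5 (exact adjusted p = 0.0380), with 500 bp windows (0.0117), with at least 500 bp covered (0.0300) and without replicate 2 (0.0340). In the pooled list and without replicate 1 it was 5 of 10 (exact adjusted p = 0.837 and 0.844).

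Of the 6 signalling pathways, 5 carried promoter peaks more often than other genes, and the retinoic acid list did not. All 16 FGF genes had one (exact adjusted p = 0.000368), with the highest signal at Spred1, an inhibitor of the Ras pathway (36.3 and 41.9), the receptor gene Fgfr2 (26.0 and 36.4) and the antagonist Spry2 (26.9 and 23.3). So did all 14 hedgehog genes (exact adjusted p = 0.000576), led by Ptch1, Foxf1 and the transcriptional effector Gli3 (29.1 and 26.9). The BMP and TGF-beta list had 21 of 23 (exact adjusted p = 0.000576), led by Smad7 (39.4 and 37.0), Smad5 (32.3 and 33.5) and Id3 (29.5 and 30.3), while the secreted antagonists Fst and Grem1 had none. The WNT list had 20 of 25 (exact adjusted p = 0.0217), with Axin2, a feedback target (42.9 and 37.5), the co-receptor gene Lrp6 (22.3 and 26.5) and Tcf7l2 (24.2 and 23.0), but not Dkk2 or Lgr5. The Notch list had 17 of 20 (Fisher's exact adjusted p = 0.0104), with Rbpj (38.6 and 30.9), Jag1 (29.2 and 28.1) and Hes1 (27.5 and 29.6), but not Dll3 or Hes5.

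Promoters of these 5 pathway lists are rich in CpG, and random genes of equal CpG content carried a peak in 76.4 to 81.8% of cases. Against them 0 of the 5 lists passed (adjusted permutation p from 0.109 to 1), and the WNT odds ratio moved from 3.12 to 0.896. The Notch call was also lost at a signal of at least 5 (exact adjusted p = 0.330). Extracellular matrix and elastic fibre genes had 22 of 24 (odds ratio 7.53, Fisher's exact adjusted p = 0.000464), with the elastic fibre genes Emilin1 (25.9 and 19.8), Mfap4 (21.6 and 23.0) and Lox (21.7 and 21.8), but not the laminin gene Lama1 or the nidogen gene Nid1. That list passed against CpG-matched genes too (adjusted permutation p = 0.00567). The retinoic acid list stood at 8 of 17 (exact adjusted p = 0.676). The receptor genes Rarg (29.9 and 34.6) and Rara (31.2 and 20.5) had peaks, and the synthesis genes Aldh1a2 and Aldh1a3 had none. Its highest promoter signal, at Rdh10 (42.0 and 42.0), belonged to a peak shared with the neighbouring ribosomal gene Rpl7.

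Genes of blood and nerve cells, which pass through or reside in lung, were marked less often or no differently. Erythroid genes had a promoter peak in 3 of 15 cases (odds ratio 0.234, Fisher's exact adjusted p = 0.0138): Tal1 (6.57 and 6.98), Nfe2 (3.70 and 4.19) and Klf1, with a peak in replicate 2 only (10.6). Gata1, Alas2 and Ank1 had none. Leukocyte genes had one in 4 of 15 cases (odds ratio 0.327, exact adjusted p = 0.0495), among them Coro1a (3.45 and 3.17), Spi1 (3.46 and 2.76) and Cd68, the last with a peak in replicate 2 only (4.35), and Adgre1 and C1qa had none. Neither list passed against CpG-matched genes, where the erythroid odds ratio was 0.644 and the leukocyte one 1.14 (adjusted permutation p = 0.542 and 1), and the leukocyte call was also lost in the pooled list and with 2.5 kb windows (exact adjusted p = 0.0823 and 0.141). Neural crest and nerve genes had 4 of 11 (exact adjusted p = 0.272), with the receptor genes Erbb3 (17.9 and 16.6) and Ednrb (8.83 and 7.36) and the myelin gene Mpz (5.93 and 6.32), but not Sox10, Foxd3 or Phox2a.

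Genes of organs other than lung were mostly unmarked. None of 18 forebrain and neuron genes had a promoter peak (exact upper limit 18.5%, Fisher's exact adjusted p = 1.01e-05), Neurod1, Dlx1 and Dlx2 included. Liver had 1 of 16 (Trf, 7.69 and 8.08, but not Afp or Ahsg, exact adjusted p = 0.000464). Gut and pancreas also had 1 of 16 (Cdh17, 3.28 and 3.66, but not Cdx1, Cdx2 or Barx1, exact adjusted p = 0.000464). Germline and pluripotency genes had 1 of 14 (Dazl, 4.33 and 6.53, but not Ddx4 or Dppa3, exact adjusted p = 0.00119). Limb and face genes had 2 of 16 (Prrx1, 8.07 and 6.86, and Prrx2, 3.07 and 3.05, but not Alx1 or Alx3, exact adjusted p = 0.00158). Kidney genes had 2 of 14, the regulators Eya1 (19.9 and 15.0) and Hnf1b (9.08 and 11.4), but not Pax2, Calb1 or Lhx1 (exact adjusted p = 0.00507). Muscle lists had the highest counts: skeletal muscle had 3 of 16 (exact adjusted p = 0.00864) and cardiomyocyte 4 of 16 (exact adjusted p = 0.0310). Without genes whose peak lay nearer to a neighbour, the muscle share was 16.7%, against 7.45% in the remaining organs. That difference did not pass (Fisher's exact p = 0.160). The cardiac genes Myh7 (9.12 and 5.24) and Tnnt2 (3.42 and 2.89) and the fast troponin gene Tnnt3 (3.75 and 4.63) had peaks of their own. So did Six1, a gene of the skeletal muscle list (4.24, in replicate 2 only). The peaks of Myl4 and Mylpf lay nearer to a neighbouring gene, and Nkx2-5, Actn2, Gata4, Myod1, Acta1 and Cav3 had none. Against CpG-matched genes the liver, skeletal muscle and cardiomyocyte calls were lost (adjusted permutation p = 0.0501, 0.0501 and 0.156). The cardiomyocyte call was also lost in the pooled list and at a −log10 q of at least 5 (exact adjusted p = 0.0524 for each), with 2.5 kb windows (0.239) and without replicate 1 (0.0937).

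As controls, all 34 cytosolic ribosomal protein genes (Rpl7, 42.0 and 42.0, Rps14, 31.1 and 20.8, and Rpl4, 24.3 and 22.9, were highest; exact adjusted p = 3.34e-08) and all 20 cell division genes had promoter peaks (exact adjusted p = 6.43e-05). The replication helicase gene Mcm7 (25.4 and 13.5), Foxm1 (a peak nearer to a neighbouring gene) and Aurkb (16.0 and 17.5) led the latter. In direct contrast, 100 of 133 lung-list genes (75.2%) and 14 of 126 other-organ genes (11.1%) carried a promoter peak (odds ratio 23.3, two-sided Fisher's exact p = 3.88e-27). Distal peaks averaged 5.92 kb per lung gene and 0.777 kb per other-organ gene, a ratio of 7.62 (permutation p = 1e-05, the smallest the permutations can give).

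**Figure D3:**
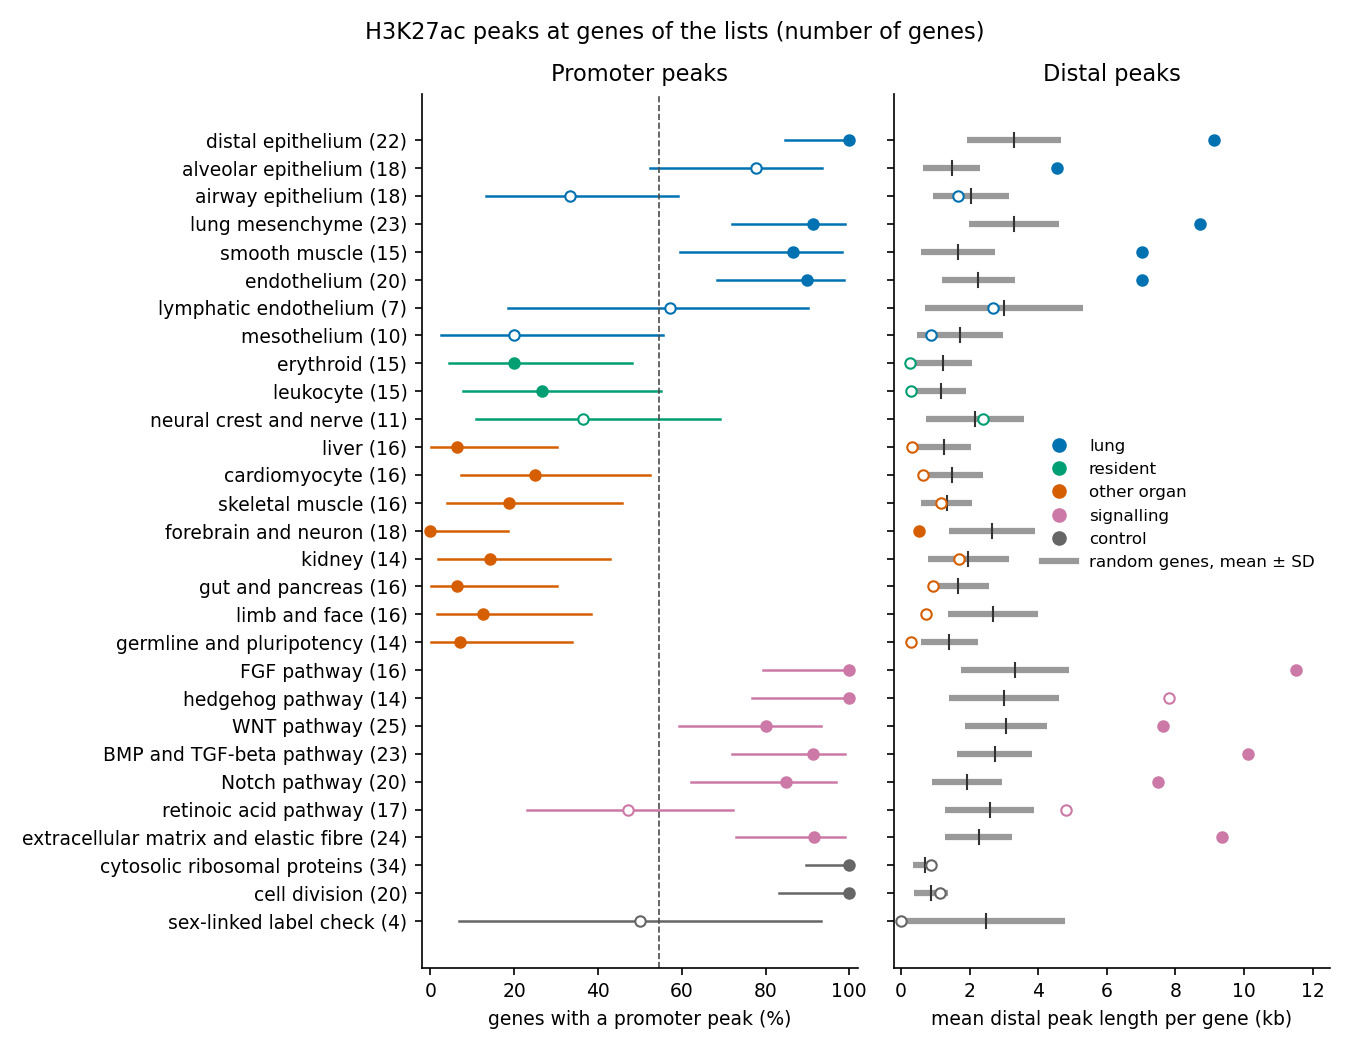
Left, percent of each list's genes with a promoter peak (dots, with 95% exact intervals as bars) against all protein-coding genes (dashed line, 54.5%); right, mean distal peak length per gene in kb (dots) beside the mean ± SD of random lists matched on territory (grey bars). Filled dots passed an adjusted p of 0.05; distal epithelium stood at 100% and forebrain and neuron at 0%.

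Distal acetylation, the length of peaks away from promoters around each gene, was longer than in random lists near genes of 10 lists, 5 of lung cell populations and 5 of signalling or matrix groups. Extracellular matrix genes had 9.36 kb per gene, 4.13 times that of random lists with equal territory (2.27 ± 0.977 kb, SD over random lists; adjusted permutation p = 0.00058). The ratio was 4.26 for smooth muscle (7.04 kb, adjusted permutation p = 0.0079), 3.90 for Notch (7.49 kb, adjusted permutation p = 0.00464), 3.70 for BMP and TGF-beta (10.1 kb, adjusted permutation p = 0.00058) and 3.45 for FGF genes (11.5 kb, adjusted permutation p = 0.00464). It was 3.11 for endothelium, 3.09 for alveolar epithelium, 2.78 for distal epithelium and 2.66 for mesenchyme, and WNT genes followed with 7.65 kb against 3.07 kb (adjusted permutation p from 0.0079 to 0.0285). Among the named genes of these lists, Smad7 had 37 distal peaks (44.7 kb), Fgfr2 had 28 distal peaks (35.0 kb), Foxa2 had 25 (32.6 kb), Tbx5 had 18 (31.8 kb), Etv5 had 29 (31.7 kb) and Hes1 had 23 (27.3 kb). Forebrain and neuron genes had 0.523 kb per gene, 0.197 times the random lists (adjusted permutation p = 0.0297).

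The hedgehog list missed the threshold (7.80 kb, ratio 2.59, adjusted permutation p = 0.0531), as did retinoic acid (1.87, 0.182). Hedgehog passed in the pooled list (adjusted permutation p = 0.0445), without replicate 1 (0.0449), without replicate 2 (0.0413) and with no territory matching (ratio 4.98, 0.00393). Ratios for lymphatic endothelium, mesothelium, airway, erythroid, leukocyte, neural crest, ribosomal, cell division, sex-linked and the other-organ lists apart from forebrain did not pass either. The alveolar and endothelial calls were lost at a signal of at least 5 (adjusted permutation p = 0.0993 and 0.0677). The alveolar call was also lost without territory matching (0.0567) and with the 500 kb limit (adjusted permutation p = 0.0593). The forebrain call was lost at a −log10 q of at least 5 (0.0566), at a signal of at least 5 (0.160) and without territory matching (ratio 0.333, adjusted permutation p = 0.288). The limb and face list passed below within 50 kb (ratio 0.160, adjusted permutation p = 0.0420). With genes matched on territory and CpG content together, limb and face (ratio 0.211), germline (0.145) and sex-linked genes (0) passed below (adjusted permutation p = 0.0179, 0.0303 and 0.0492). The sex-linked list also did in the pooled list (adjusted permutation p = 0.0445). It holds 4 Y genes, and the whole Y chromosome carried 3 replicated and 4 pooled peaks, while the random genes came from all chromosomes. Its result may thus belong to the Y chromosome and not to these genes.

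Hox genes, which pattern the body axis by paralog group, were marked at their anterior members. Hoxa1 to Hoxa5 and Hoxb2 to Hoxb5 all had promoter peaks, from 6.75 and 7.66 at Hoxa3 to 24.7 and 25.6 at Hoxb3 and Hoxb4, which lay with Hoxb5 under a single replicated peak of 44.0 kb (chromosome 11, 96303490 to 96347489). Hoxa5, a factor required for normal tracheal and lung development, had signals of 13.2 and 9.98. Of groups 6 to 8, Hoxa6, Hoxb6, Hoxb7 and Hoxb8 were marked (4 of 8). None of the 16 genes of groups 9 to 13 had a peak, and no Hoxc or Hoxd gene of any group did. Groups 1 to 5 (9 of 15) differed from groups 9 to 13 (0 of 16) with an odds ratio of 48.2 (two-sided Fisher's exact p = 0.000248). Genes of a cluster are neighbours and can share peaks, so they are not independent.

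**Figure D4:**
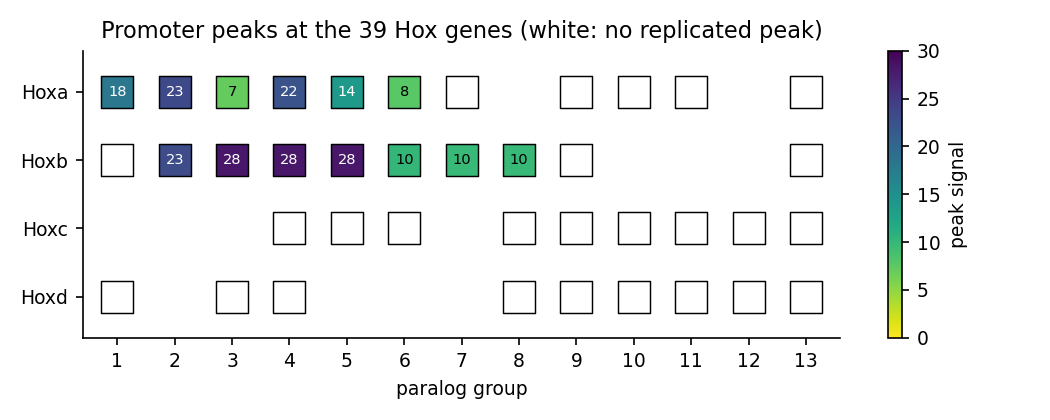
Map of the 39 Hox genes by cluster (rows) and paralog group (x axis); colour and number give the signal of the strongest replicated promoter peak, and white squares had none. Peaks cover 9 of 15 genes in groups 1 to 5 and 0 of 16 in groups 9 to 13.

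Joining distal peaks into domains gave 18030 domains, of which 760 were top-ranked and held 37.6% of the summed signal. The 10 highest lay nearest to Cstad (chromosome 2, 30636561 to 30726115), Zfp36l1 (chromosome 12, 79878254 to 80023612), Bcas3 (chromosome 11, 85663715 to 85828119), Tex44 (chromosome 1, 86433330 to 86506537), Scyl1 (chromosome 19, 5781497 to 5852776), Ly86 (chromosome 13, 37434247 to 37515305), Irf2bp2 (chromosome 8, 126633130 to 126767973), Ddc (chromosome 11, 11815095 to 11887787), Btg2 (chromosome 1, 134042046 to 134106769) and Irf2bpl (chromosome 12, 86769654 to 86873068). None of these nearest genes is on a list. Those of Bcas3 and Ddc were centred inside the gene and the other 8 outside.

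The 760 domains had 673 nearest genes, and 10 of the 29 lists held more of them than other genes did, 3 of these among the 8 lung lists. Genes with more surrounding sequence can be nearest to more domains, and this test was not matched on territory. Mean territory per gene ran from 61.1 to 151 kb over the called lists and from 32.5 to 130 kb over the others. The odds ratios may therefore partly reflect territory. Mesenchyme had 8 of 23 genes (Tbx3, Tbx5, Wnt2 and Macf1 among them; odds ratio 17.4, Fisher's exact adjusted p = 7.39e-06). Distal epithelium had 6 of 22, including Nkx2-1, Foxa2, Sox9 and Etv5 (exact adjusted p = 0.000298). WNT genes had 7 of 25 and matrix genes 7 of 24 (exact adjusted p = 7.34e-05 for each), BMP and TGF-beta genes 6 of 23, with Smad7 and Id3 (exact adjusted p = 0.000314), and FGF genes 5 of 16, with Fgfr2 and Spry2 (exact adjusted p = 0.000437). Notch (4 of 20), hedgehog (3 of 14), retinoic acid (3 of 17) and alveolar epithelium (3 of 18) passed less clearly (exact adjusted p from 0.0121 to 0.0489). Smooth muscle (2 of 15), endothelium (2 of 20), lymphatic endothelium (1 of 7), airway (0 of 18) and mesothelium (0 of 10) did not pass (exact adjusted p from 0.202 to 1). At a signal of at least 5 the calls of Notch, hedgehog, retinoic acid and alveolar epithelium were lost (exact adjusted p from 0.619 to 1). In each replicate's own list those of retinoic acid and alveolar epithelium were lost (Fisher's exact adjusted p from 0.0534 to 0.247). Among the top 500 domains the matrix call was lost (3 of 24, odds ratio 7.68 from 13.6, exact adjusted p = 0.0545). The alveolar epithelium call was lost too (odds ratio 4.03 from 7.12, exact adjusted p = 0.610). Those of hedgehog (9.42 from 9.60, exact adjusted p = 0.121) and retinoic acid (7.60 from 7.61, exact adjusted p = 0.155) were lost with the odds ratio nearly unchanged. With joining within 5 kb the calls of hedgehog (0.0699), alveolar epithelium (0.122), Notch (0.143) and retinoic acid (exact adjusted p = 0.389) were lost. Ranked by length alone, retinoic acid (0.0692) and alveolar epithelium (0.379) were lost, and endothelium passed with 6 of 20 (exact adjusted p = 0.000381).

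Distal peaks carried binding words of several transcription factor families more often than flanks of equal GC content. TEAD words, the sites of the effectors of Hippo signalling, occurred in 16.8% of 48442 peak windows against 11.6% of control windows (odds ratio 1.54, 95% interval 1.49 to 1.60, Fisher's exact adjusted p = 2.03e-118). FOX words of forkhead factors were in 14.5% against 10.8% (odds ratio 1.40) and ETS words in 11.9% against 8.56% (1.44). The E-box CAGCTG was in 31.9% against 25.3% (1.39), CEBP words in 3.66% against 2.33% (1.59) and MEF2 words, sites of muscle regulators, in 0.929% against 0.452% (2.06). In all, 20 of 26 words were more frequent and 3 less frequent: T-box (odds ratio 0.729), PBX-MEIS (0.833) and the NeuroD E-box (0.942). The comparison with each word read in reverse left 12 words above, the NeuroD E-box among them. For CEBP, NFI, CTCF and POU words and CAGCTG every form of the reversed word holds a CpG. The words themselves hold none, or for CEBP and NFI only in some forms. The GRHL word holds a CpG that its reverse lacks. ETS and STAT words hold one in some forms, and their reverses never do. The reverse is a poor control for all of these words. GLI, HNF4 and POU words did not pass. NK2 words, the sites of Nkx2-1, were in 7.57% against 6.68% (odds ratio 1.14, exact adjusted p = 1.23e-07). The reversed NK2 word was enriched as much, and the call was lost against it (ratio of odds ratios 1.02). Calls of AP-1 (1.05), KLF-SP (0.980), SRF-CArG (0.983), GRHL and PBX-MEIS (0.911) words were lost there too. Those of NFI (2.85), HNF1 (2.15) and CTCF (1.89) were lost while the ratio stayed high, in few windows, so their specificity is left open. SOX words turned from 1.17 to 0.918 and the NeuroD E-box from 0.942 to 1.28 in the same comparison. There the reversed SOX word was itself more frequent in peaks (odds ratio 1.27) and the reversed NeuroD word less frequent (0.737). Whether these reversed words are sites of other factors was not tested. The comparison therefore leaves open whether the SOX excess and the NeuroD shortage are specific to the word. Windows are neighbours within domains and not independent, so p-values of this size rank words and are not to be read as probabilities.

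**Figure D5:**
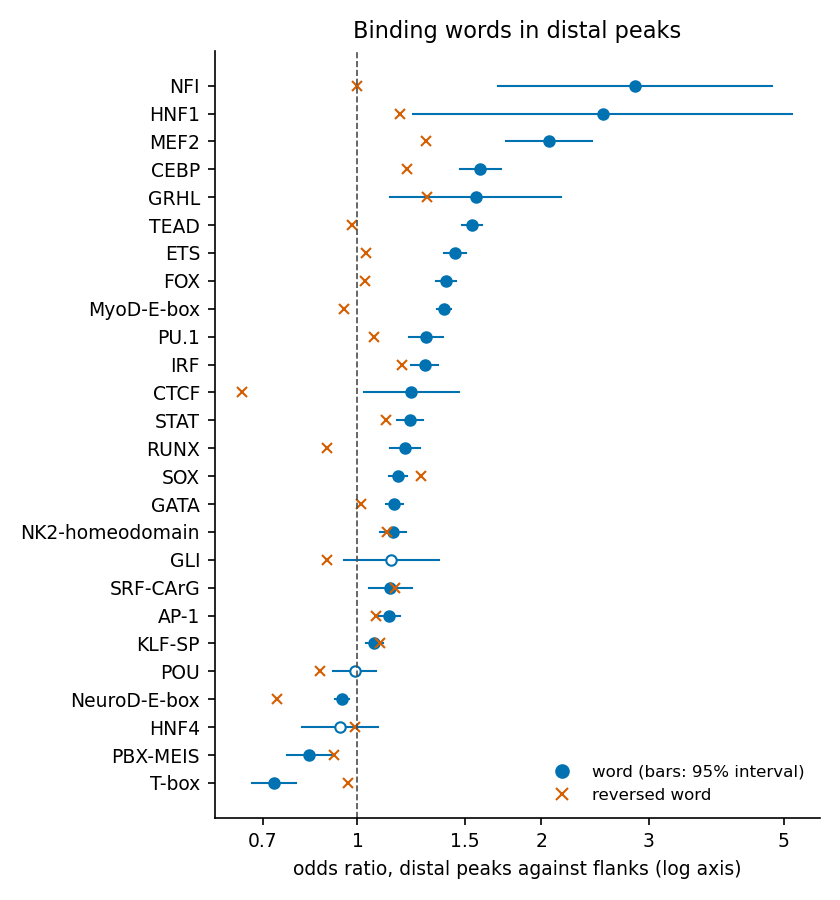
Odds ratio of each binding word in distal peak windows against GC-matched flanks (dots, 95% interval as bars, log axis) beside that of the reversed word (crosses); filled dots passed an adjusted p of 0.05. TEAD (1.54), FOX (1.40) and ETS (1.44) words stand clear of their reversed words, whereas the NK2 and SOX words do not exceed theirs by much or at all. Some forms of the ETS word hold a CpG that its reverse lacks, so that reverse is a poor control.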

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

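Some tests in this part were chosen only after the related results were seen. They are the CpG matching of distal peaks, the test of every peak belonging to a neighbour and the muscle comparison. The CpG matching of promoters was planned, but the rule for reading it was set after its result was seen. The replicated list held 8 peaks on 5 sequences outside the main chromosomes (signals from 1.78 to 50.6), and these sequences enter no comparison.

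The promoters of the FGF, hedgehog, WNT, BMP and TGF-beta and Notch lists carried peaks more often than other genes. Promoter CpG content is a candidate explanation: against random genes of equal CpG content 0 of the 5 lists stayed past the threshold, and the matched genes carried peaks in 76.4 to 81.8% of cases against 54.4% to 54.5% of all other genes. Lists at or near 100% leave little room above such a background, so the tests for FGF (odds ratio 8.56, from 27.6 before matching) and hedgehog (8.50, from 24.3) also had low power. Matching on CpG content did not remove the distal excess. All 4 pathway lists called there stayed past the threshold with genes matched on territory and CpG content together (ratios 2.07 to 3.45, adjusted permutation p from 0.00174 to 0.0244). Each of the 4 ratios was lower than with territory matching alone, so CpG content may go with part of the excess. The joint matching was also coarse, with 5 classes in place of the territory deciles, so the size of that part stays open. No biological explanation was tested, because the design holds 1 group.

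Some genes of other organs carried a promoter peak, 14 in all. A neighbouring gene may account for part of this: for 2 of the 14 (14.3%), Myl4 beside Cdc27 and Mylpf beside Tbc1d10b, the peak was centred nearer to another gene's start, against 1.00% of the 100 lung-list genes (Fisher's exact p = 0.0394). The other 12 (85.7%) had it nearest to their own start, so a nearer protein-coding neighbour does not account for them. That outcome was likely beforehand, because the genes were picked for a peak within 1 kb of their start. Starts of RNA genes were not searched, so other neighbours stay open. Heart or skeletal muscle tissue in the samples stays open: the muscle lists had peaks of their own in 16.7% of 30 genes and the remaining organs in 7.45% of 94 (Fisher's exact p = 0.160; 21.9% and p = 0.0451 with Myl4 and Mylpf kept). Dissected tissue beside lung and heart muscle that belongs to lung, such as the sleeves of the pulmonary veins, were not told apart by any test. Nor do peaks from whole lung show which cells carried these marks, and the list a gene stands on does not settle it.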

How the results depend on the processing

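The matching on territory and CpG content together was chosen after the data were seen; the other alternatives were planned. The contrast of lung with other-organ lists and the Hox comparison kept their direction and side of the threshold in every alternative run (promoter odds ratio 17.2 to 34.1, distal ratio 6.80 to 8.93, Hox odds ratio 48.2 throughout). Matching on promoter CpG content was not run for either of them. The replicate difference by list could not pass in any setting and says nothing on stability. Of the lists, 6 of 12 called above and 5 of 10 called below at promoters were called in every alternative, 8 of 10 above for distal length and 5 of 10 above for domains; of the words, 10 of 20 above and 1 of 3 below. Among all 902 single values recomputed, 784 kept their side of the threshold, 62 fell back over it, 24 passed it, 20 shares moved and 12 turned direction; turns of values past the threshold in neither run count among the 784.

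Sharing between replicates fell to 57.3% and 60.2% when 50% of the peak had to be covered, and at a −log10 q of at least 2 it was 72.3% for replicate 2 with a Spearman coefficient of 0.753. The promoter share of peaks was 18.0% in the pooled list, 28.2% at a −log10 q of at least 5, 41.8% at a signal of at least 5, 23.0% and 29.0% with windows of 500 bp and 2.5 kb, and 19.7% to 20.2% without a replicate; wider windows include more by construction. Matched on promoter CpG content, 6 lists were below (5 of the 10 called before, and mesothelium), and the odds ratio turned to 1.14 for leukocyte and 0.896 for WNT. Distal lists below numbered 2 in the pooled list and within 50 kb, 0 at a −log10 q of at least 5, at a signal of at least 5 and with no territory matching, and 4 with territory and CpG content matched. Lists above for domains numbered 6 with joining within 5 kb, for the top 500 domains and at a signal of at least 5.

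Words above numbered 11 within 100 bp and 12 against the reversed word. Within 100 bp the odds ratio was lower for TEAD (1.19, from 1.54), FOX (1.19, from 1.40) and ETS words (1.12, from 1.44). It was also lower for CEBP (1.22, from 1.59), CAGCTG (1.26, from 1.39) and MEF2 words (1.45, from 2.06), and for the other words still above there. Among words called in either run, the odds ratio turned within 100 bp for KLF-SP (0.790), HNF1 (0.778), CTCF (0.491), GRHL (0.726) and PU.1 (0.987), and over the whole peak for CTCF (0.652). Against the reversed word it turned for SOX (0.918), KLF-SP (0.980), NeuroD (1.28) and SRF-CArG (0.983). Except where construction is named, the cause was not tested. Unknown read depth limits every statement about genes without a peak, and the leave-out of a replicate swaps the replicated list for the other replicate's own, longer list.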

Other observations

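The genes and peaks of the first 2 paragraphs were chosen after their values were seen, and the 4 tests of words by nearest gene were planned before their results were. Several of the strongest or longest acetylated regions lie at RNA genes without a protein product or beside regulators that nearest-gene naming hides. The domain named for Bcas3 ended 4.43 kb from the start of Tbx2 and 58.3 kb from that of Tbx4, both T-box genes of lung mesenchyme, and a replicated peak of 19.3 kb covered Tbx2 (chromosome 11, 85828555 to 85847865). The domain named for Scyl1 covered the nuclear RNA genes Malat1 and Neat1, and a peak of 13.6 kb lay over Malat1 (chromosome 19, 5799663 to 5813230). A peak of 11.8 kb (chromosome 18, 61651111 to 61662935; signal 18.6) lay over Carmn, an RNA gene of cardiac and smooth muscle cells, 30.9 kb from the nearest protein-coding start, that of Il17b. A peak of 9.73 kb with signal 19.1 covered the imprinted RNA gene H19 and its microRNA gene Mir675 (chromosome 7, 142568420 to 142578154).

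The longest replicated peaks after the 44.0 kb block at Hoxb3 to Hoxb5 and that at Tbx2 lay at Smad7 (15.0 kb, signal 44.1), at Malat1 as above, and at the laminin gene Lama5 (12.8 kb, 14.2). Next came Tnrc18 (12.3 kb, 49.3), Id3 (11.9 kb, 32.7), Carmn as above and Fam129b (11.4 kb, 18.1), then the region of the RNA gene 9430078K24Rik, 183.1 kb from Zfp36l1 (11.4 kb, 14.0). Zmynd8 (11.1 kb, 38.2), Hes1 (11.0 kb, 31.5) and Zeb2 (10.8 kb, 20.8) followed. Apart from lists, 2335 genes had distal peaks nearest to them but no promoter peak.

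A hypothesis was that distal peaks near genes of a cell type carry the word of a factor known to act there more often than peaks near random genes with as many distal peaks. For the CArG word bound by Srf near smooth muscle genes the values go with it: 10 of 105 distal peaks (9.52%) held the word against 2.56% near random genes (ratio 3.72, permutation p = 0.00084, adjusted p = 0.00336 over 4 tests). The 10 peaks lay near 7 genes, with 3 at Mylk, 2 at Synpo2 and 1 each at Acta2, Foxs1, Lmod1, Myh11 and Smtn. This may reflect direct control by Srf, which peak lists cannot show, and the count is small. FOX words near epithelial genes (18.6% of 279 peaks against 14.1%, permutation p = 0.0387, adjusted p = 0.0773) missed the threshold after adjustment. So did NK2 words near the same genes (9.68% against 7.54%, adjusted permutation p = 0.284) and ETS words near endothelial genes (13.7% of 175 peaks against 11.8%, adjusted permutation p = 0.440); these counts leave the question open.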
